A study of Rattus norvegicus with 2 samples.

How the data were processed

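Droplet single-cell RNA sequencing of rat meniscus was analysed from 1 aged and 1 young library. Per the labels' protocols, tissue was minced, digested with protease and then collagenase P, strained, sorted by flow cytometry for viable cells and processed with a 10x Genomics 3' kit. The deposited matrices hold UMI counts per gene and barcode, whole numbers that were not normalised. Cell Ranger 6.1.1 is named per the file headers and in the submitters' processing notes; the genome build and annotation are not given in the sources used here. Each library lists 25399 genes and called-cell barcodes only, none with under 500 UMIs. Gene names were taken from the files.

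Cells were kept with at least 500 genes and at most 20% of counts from the 13 mitochondrial genes. This removed 2337 of 8422 aged and 1141 of 9914 young barcodes. Scrublet, run per library in scanpy 1.11.5, called 0 aged and 3 young cells doublets, too few for a working call at this number of cells. The 3 cells were left out, doublets otherwise remained, and an alternative left out the top 8% of doublet scores in each library. Cells of both libraries were clustered together on log-normalised counts (10000 UMIs per cell), 2000 variable genes chosen within each library, 30 principal components, shared nearest neighbours among 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1. A cluster took the name of the fixed marker list with most genes among its 10 leading genes by fold, given at least 3 markers found in 10% of its cells and either 3 markers enriched 1.5-fold or 2 among the leading genes. Without such a leading gene it needed at least 3 markers enriched 1.5-fold that made up 40% of a list; 4 B cell-like clusters and 1 neutrophil-like cluster were named so. Other clusters stayed unnamed. The marker lists were fixed beforehand, these naming thresholds were not.

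Raw counts were summed per library and class. The aged over young ratio of CPM (counts scaled to 1000000 UMIs) was given on the log2 scale with an exact conditional binomial 95% interval. Shares carry Clopper-Pearson intervals, and a share of 0 is given with the limit of 3 counts of the total. All intervals cover counting error only, and no test, standard error or p-value was made from cells. A gene with 0 counts in a library was set against a floor of 3 counts and given as a bound, and no fold was given when both libraries were at or under 3 counts. Classes with at least 50 cells in each library were compared, and the chondrocyte-like class with 39 aged cells because it was a planned comparison of its own.

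Named genes followed a rule fixed before the data were examined, as were the groups, markers, gene lists and most other settings tried. Among genes with at least 50 CPM in the higher library and 100 summed counts, the 12 largest ratios in each direction were named in the chondrocyte-like class and the 5 largest in each other class. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and uncharacterised genes were left out of this ranking. Atf3, Cdkn1a, Cdkn2a, Col1a1, Col2a1, Acan and Prg4 were fixed for every class, with up to 4 members per list. Some genes that these rules select are not reported here. Egr1, Fos and Jun in chondrocyte-like cells, RT1-Ba in macrophage or monocyte-like and B cell-like cells, Mzb1 and Cd79b in T or NK cell-like cells, and the beta-globin genes other than Hbb fall outside these rules and were chosen after their values were seen. For each list, the median log2 ratio of members with at least 20 summed counts was set among 10000 random lists matched on expression, with an order-statistic 95% interval over members. Members at least 1.5-fold apart were counted by size alone.

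Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, leaving out shallower cells. Alternatives covered the cell filter, doublets, resolution, separate clustering of each library, clustering without stress genes, edgeR 4.0.16 TMM and DESeq2 1.42.0 median-of-ratios scaling, other totals, per-cell means, thinning and the count minimum. Alternatives on the make-up of the classes, on doublet scores and on genes of classes other than chondrocyte-like cells were added after the data were seen.

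The comparison was tested on simulated data drawn from the pooled chondrocyte-like profile at the real totals. Of 6750 unchanged genes, 96.9% of intervals held no change. Among 100 genes changed by 2-fold the interval excluded no change in 79%, with a median recovered log2 size of 0.98, and among 100 changed by 4-fold in 100%, with 2.05. Of 25 lists without effect, 24 lay between the outer 2.5% tails. The counts were independent Poisson draws, the model behind the interval, without variation between cells, subtypes or animals. The simulation therefore checks the computation and cannot show how the intervals or list percentiles hold for the real cells. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.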

Results

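Single-cell RNA profiles of rat meniscus, the fibrocartilage pad of the knee, were compared between 1 library from aged and 1 from young tissue. The labels give no strain, sex or number of animals. The aged library held 8422 barcodes and 47228750 UMIs, and the young library 9914 barcodes and 65051972 UMIs. After filtering, 6085 aged cells with a median of 3686 UMIs and 8770 young cells with a median of 3845.5 UMIs were kept. With 1 library per age no test across animals could be made. Values are therefore given for both libraries with exact 95% intervals, which cover counting error only, and every difference is between these libraries.

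The first question was which cells the tissue yielded. Most cells in both libraries carried markers of blood or marrow cells. B cell-like cells made up 41.4% of aged (95% interval 40.1 to 42.6) and 56.3% of young cells (55.3 to 57.3). Neutrophil-like cells made up 13.0% of aged (12.2 to 13.9) and 12.9% of young cells (12.2 to 13.7). Macrophage or monocyte-like cells were 10.3% of aged (9.54 to 11.1) and 4.75% of young cells (4.32 to 5.22), and T or NK cell-like cells 3.76% (3.30 to 4.27) and 1.28% (1.05 to 1.53). Proliferating cell-like cells were 9.24% of aged and 13.5% of young cells, erythroid-like cells 1.53% and 2.35%, and mast cell-like cells 0.362% and 0.274%. The named blood classes, without the proliferating cells, summed to 70.4% of aged and 77.9% of young cells. With at least 1000 genes and at most 10% mitochondrial counts the aged B cell-like share was 23.9%, the aged macrophage or monocyte-like share 16.1% and neutrophil-like shares 3.73% and 4.49%, while 29.7% of aged and 16.2% of young cells stayed unnamed. At resolution 0.5 macrophage or monocyte-like cells were 4.24% of aged and 2.46% of young cells, and with at least 200 genes erythroid-like cells were 4.03% and 4.95%. Proliferating cell-like shares lay between 4.47% and 14.8% in aged and 8.11% and 14.9% in young cells over the settings tried, and mast cell-like shares reached 0.883% and 1.24%.

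Stromal cells were a small part of each library. The chondrocyte-like class, named from Col2a1, Snorc, Chad and other cartilage genes, held 39 aged cells (0.641%, 0.456 to 0.875) and 150 young cells (1.71%, 1.45 to 2.00). The fibroblast-like class held 517 aged cells (8.50%, 7.81 to 9.23) and 84 young cells (0.958%, 0.765 to 1.18). Endothelial-like cells were 0.641% of aged and 0.137% of young cells, and 10.6% of aged and 5.85% of young cells stayed unnamed, most of them in a cluster led by the B cell precursor genes Igll1, Vpreb2 and Vpreb1 (6.36% and 4.26%). No order is read from the chondrocyte-like and fibroblast-like shares, because the genes that lead these clusters differed between the libraries themselves. Clustering each library on its own moved the aged chondrocyte-like share to 7.89%, since the main aged stromal cluster then took that name, and the aged fibroblast-like share to 0.904%, while 1000 genes and 10% mitochondrial counts gave 14.6%. Cells were also sorted for viability before loading, a step that can set shares. Different clusters held most of a class in the libraries: clusters 3 and 9 against 0 and 1 for B cell-like cells, cluster 8 against 23 for fibroblast-like cells, and clusters 13 and 4 against 6 and 4 for neutrophil-like cells.

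**Figure D1:**
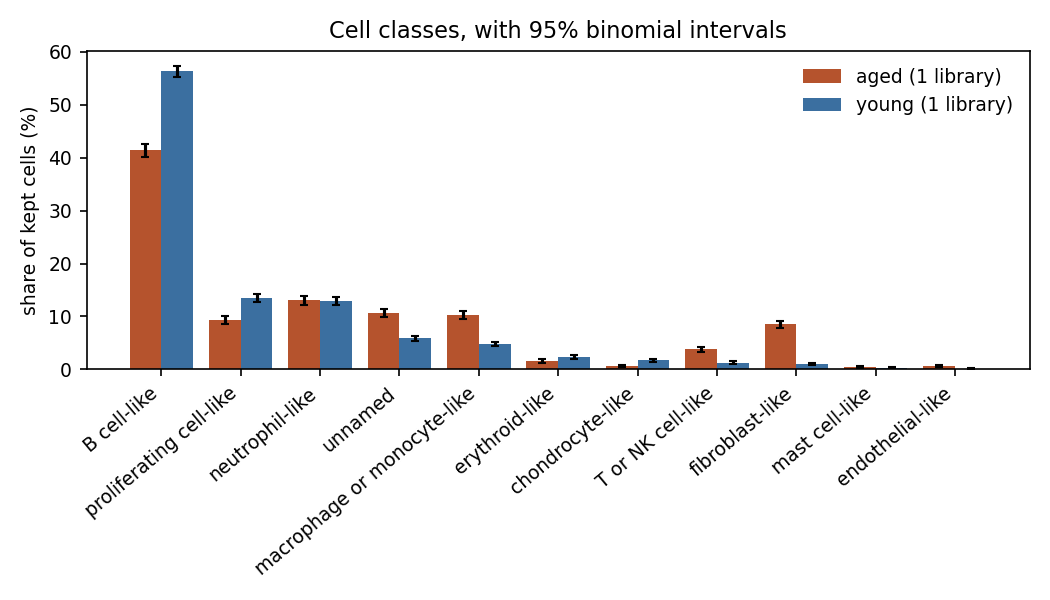
Share of kept cells (%, y axis) in each cell class (x axis) for the aged and the young library; bars are single libraries and error bars are exact 95% binomial intervals. B cell-like cells are the largest class in both, at 41.4% of aged and 56.3% of young cells, and chondrocyte-like cells are 0.641% and 1.71%.

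The main comparison asked how chondrocyte-like cells differed with age. In the aged library these cells carried more RNA for secreted inflammatory factors, at 1.32% of UMIs (1.28 to 1.37) against 0.219% in young cells (0.213 to 0.225). In the stromal subcluster shared by both libraries, described below, the shares were closer, at 1.49% of aged and 0.937% of young UMIs. There Cxcl1 alone gave 2086 of the 3277 aged and 1 of the 3417 young UMIs of the list. The higher aged share in that subcluster therefore rests on Cxcl1. Its 28 young cells held 3417 of the 5010 young UMIs that the list had in the whole class. Aged chondrocyte-like cells carried less for 18 of 27 cartilage matrix genes by at least 1.5-fold. That list as a whole nevertheless took 6.30% of aged (6.22 to 6.39) and 6.99% of young UMIs (6.95 to 7.02). Cxcl1, a neutrophil-attracting chemokine, stood at 7311 CPM (counts scaled to 1000000 UMIs) in aged and 17.5 CPM in young cells, a log2 ratio of 8.71 (8.26 to 9.20). Col2a1, the main collagen of cartilage, stood at 41.3 and 7932 CPM, a log2 ratio of -7.59 (-8.54 to -6.78). Atf3, a stress-induced transcription factor, stood at 1589 and 519 CPM, a log2 ratio of 1.61 (1.46 to 1.77). The sums behind these values were 290776 UMIs in 39 aged cells and 2289047 UMIs in 150 young cells.

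The 12 genes with the largest ratios towards aged included, besides Cxcl1, Serpina1, a protease inhibitor (log2 ratio 5.59), Gpx3, a secreted glutathione peroxidase (4.42), Ptgs2, the inducible cyclooxygenase (4.06), Angptl7 (3.98) and Cytl1, a cartilage cytokine-like protein (3.58). The small leucine-rich proteoglycans Lum and Dcn were higher by 4.82 and 4.06, the class I gene RT1-A1 by 4.51, the early response gene Ier3 by 3.96 and the chemokine receptor Ackr3 by 3.56. Over the alternatives tried all of these but Angptl7 kept their direction, with the lowest ratios at 5.04 for Cxcl1, 2.36 for Serpina1, 1.09 for Lum, 0.97 for Dcn and 0.24 for Cytl1. Prg4, which encodes the joint lubricant lubricin, was higher by 1.06 (1.02 to 1.10), but lower at -1.87 with each library clustered on its own.

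The 12 genes with the largest ratios towards young included 5 collagen genes, Col2a1 among them. Col9a2 was lower in aged cells by a log2 ratio of -6.67, from 4 aged counts. Col9a3 (-5.77, -11.08 to -3.29), Col6a1 (-5.41, -10.72 to -2.92), Cthrc1 (-5.38, -10.68 to -2.89) and C1qtnf1 (-5.35, -10.66 to -2.86) each rest on 1 aged count. Col9a1, Tnni2 and Cpz had no aged count and were at least 75.3-fold, 69.4-fold and 42.9-fold lower. Col1a1, the main collagen of fibrous tissue, was lower by -4.70 (-5.06 to -4.35), and Acan, the large proteoglycan of cartilage, by -2.28 (-2.82 to -1.79). The neutrophil or macrophage genes Camp (-5.47, -10.77 to -2.98, 1 aged count), Defa5 (-5.27, -10.58 to -2.78, 1 aged count) and Lyz2 (-5.24) also stood among the 12. Camp turned to 0.93 with each library clustered on its own and to 0.38 over chondrocyte-like and fibroblast-like cells together. Col9a2 turned to 0.18 in the stromal subcluster shared by both libraries when stress genes were left out of its clustering, and the ratios nearest to 0 under any alternative were -0.23 for C1qtnf1, -0.45 for Lyz2, -0.49 for Col9a3 and -0.92 for Col6a1. The neutrophil gene S100a8 was at 72.2 CPM in aged and 946 CPM in young cells, and at 60.0 and 203 CPM in the 38 aged and 132 young cells without a UMI of the leukocyte gene Ptprc.

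**Figure D2:**
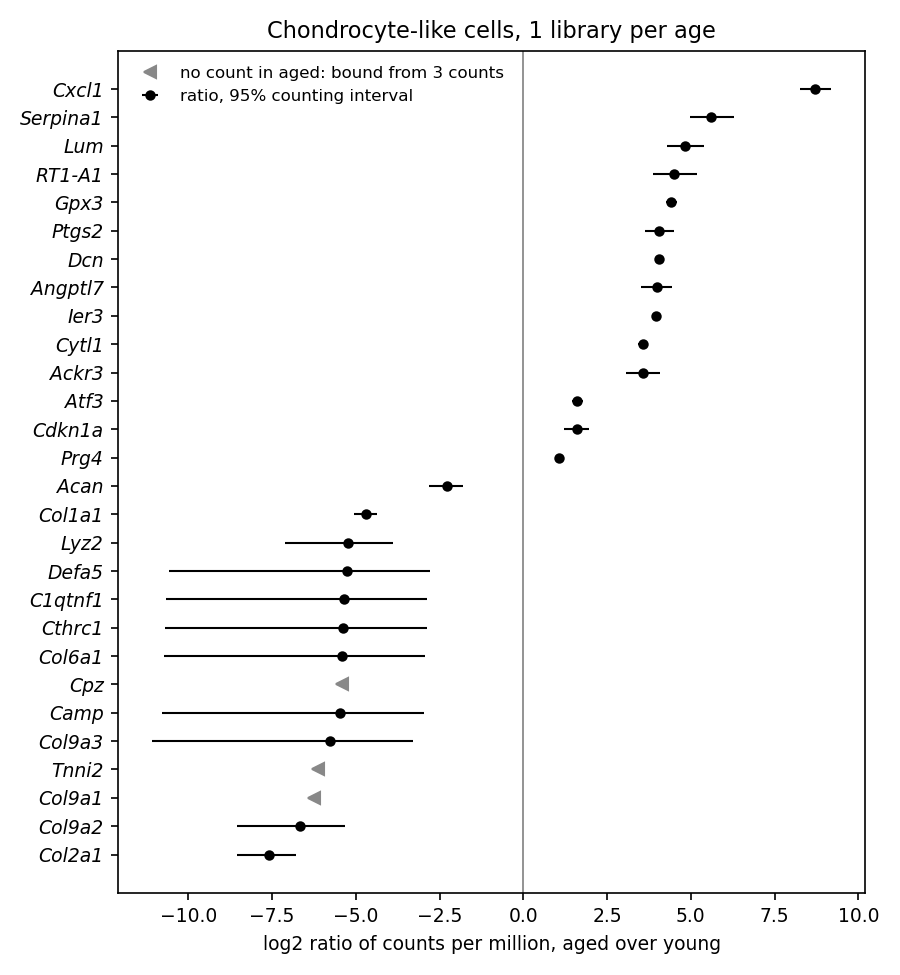
Log2 ratio of CPM, aged over young (x axis), for the named genes (y axis) in chondrocyte-like cells, 1 library per age; points carry 95% counting intervals and triangles are bounds for genes with no aged count. Ratios run from 8.71 for Cxcl1 to -7.59 for Col2a1, with Atf3 at 1.61.

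The secreted inflammatory and complement lists had the highest medians. The secreted inflammatory list had a median log2 ratio of 2.44 (0.94 to 3.48 over members), above all 10000 expression-matched random lists, with 15 of 17 measured members at least 1.5-fold higher in aged, among them Cxcl1, Ptgs2 and Hmox1 (3.48), while Cxcl10 was at least 63.0-fold higher. In the stromal subcluster shared by both libraries its median was 3.08 (-1.30 to 4.13), with 9 of 13 members higher and 3 lower. The list also stood above all random lists in every other compared class except proliferating cell-like cells (-0.15, percentile 36.2). In macrophage or monocyte-like cells the median was 1.85, with 24 of 28 members higher, so the rise is not particular to chondrocyte-like cells. Erythroid-like cells had a median of 3.07 over 9 members, with Cxcl1 at 63 aged and 2 young counts and Lcn2 at 76 and 26. How far such counts were free RNA of the library was not tested. No list is singled out in B cell-like cells, as described below. The AP-1 and immediate early list had a median of 1.14 (0.023 to 1.75, percentile 100), with 21 of 38 members higher and 6 lower by that size. Atf3, which the study picked on these libraries, is a member. The members went both ways: Ier3, Nfkbia (3.47), Irf1 (3.46), Maff (3.25) and Egr1 (1.39) were higher, and Fos (-0.87) and Jun (-0.61) lower. Complement genes had a median of 1.99 (0.20 to 3.89, percentile 100), led by C3 (3.89) and Clu (3.28). Interferon response genes had a median of 1.02 (-0.44 to 2.26, percentile 100), with Bst2 at 3.68 and Ifitm3 at 2.26. Antioxidant genes had a median of 0.54 (percentile 99.99), with Gpx3 and Sod2 (2.95). In the shared subcluster the medians were 0.96 (-1.17 to 1.62, percentile 97.2) for complement and 1.04 (-2.38 to 5.14) for interferon response.

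The senescence and cell cycle arrest list had a median of 0.46 (-0.29 to 1.82, percentile 98.4), with 6 of 15 members higher and 2 lower. Gadd45g (2.55) and Gadd45b (2.51) were higher, and Glb1, the gene of lysosomal beta-galactosidase, was lower at -1.94. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 279 CPM in aged and 92.6 CPM in young cells (log2 ratio 1.59, 1.20 to 1.96). Cdkn2a, the gene of p16, had 0 counts in both libraries. In the stromal subcluster that held chondrocyte-like cells of both libraries, chosen after seeing the data, the Cdkn1a ratio was 0.39 with an interval of -0.064 to 0.84, and over chondrocyte-like and fibroblast-like cells together it was 0.044. With each library clustered on its own it was -0.058.

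Matrix lists stood at the other end. Cartilage matrix had a median of -2.26 (-3.25 to -0.27) and fibrous matrix of -1.32 (-2.55 to 0.38), both below all random lists, with 18 of 27 and 17 of 26 members lower. The fibrous list took 3.01% of aged and 7.25% of young UMIs, whereas the shares of the cartilage list were close, with Prg4, Cytl1 and other members higher. Sparc (-5.07) was lower with Col1a1 in the fibrous list, in which Lum was higher. Collagen processing genes had a median of -1.47 (percentile 0), with 15 of 20 members lower and 0 higher, among them P3h1 (-4.33, -6.61 to -2.77, 3 aged counts) and the collagen chaperone Serpinh1 (-2.81). Nuclear oxidative phosphorylation genes had a median of -0.37 (percentile 0.74). The median over all 6993 measured genes was itself -0.25, so that TMM scaling would add 0.21 to each log2 ratio. With each library clustered on its own the fibrous matrix median was 1.03 and that of oxidative phosphorylation 0.099.

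Medians of the other lists were 0.34 for heat shock (percentile 96.7), in which Hspb1 was at 3.17, 0.12 for the unfolded protein response (91.4), 0.41 for matrix proteases (98.5), where Plau was at least 126-fold higher and Mmp3 higher by 2.32, and -0.34 for hypertrophy (17.0). They were -0.056 for chondrogenic regulators (58.2), 0.32 for progenitor genes (95.2), -0.17 for glycolysis and hypoxia (39.6), 0.32 for antigen presentation (96.3) and -0.38 for lysosome and autophagy (7.23), which turned to 0.31 with each library clustered on its own and to 0.18 over chondrocyte-like and fibroblast-like cells together. Cell cycle genes had a median of 0.46 (99.4), TGF-beta and YAP targets 0.30 (97.1), lipid genes 0.31 (97.2) and cytosolic ribosomal proteins 0.11 (68.5). The blood list had a median of -0.72 (3.02) and the sex-linked list of -0.48 (38.0), the latter over 5 genes. In the shared stromal subcluster the sign turned for progenitor genes (-1.34, percentile 0.705), matrix proteases (-0.44), the unfolded protein response (-0.31, 25.2) and the blood list (0.71, 98.7). Heat shock, hypertrophy, chondrogenic, glycolysis, cell cycle, lipid and sex-linked medians turned under other alternatives, so no direction is read from those of these lists that turned.

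**Figure D3:**
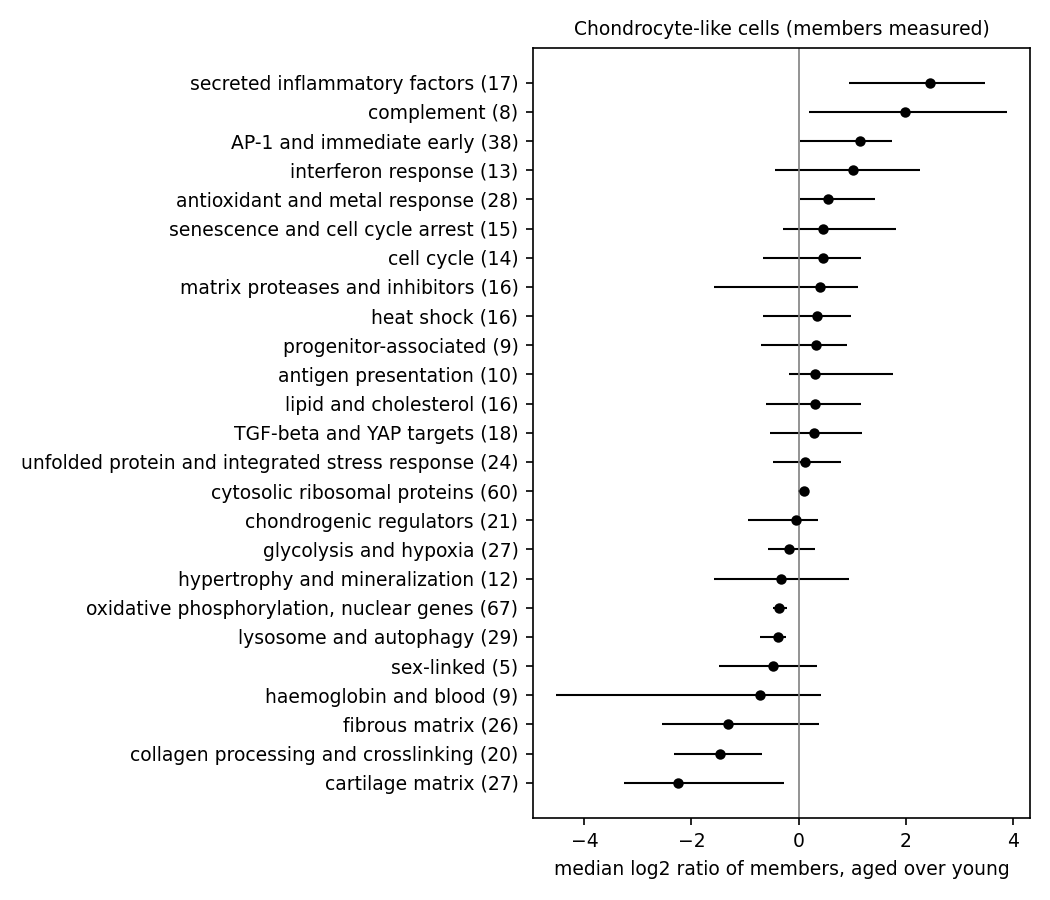
Median log2 ratio of each gene list (x axis) in chondrocyte-like cells, with the number of measured members beside its name (y axis); bars are 95% order-statistic intervals over members. Secreted inflammatory factors lie highest at 2.44 and cartilage matrix lowest at -2.26.

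The class differed in make-up between the libraries, which bears on every value above. When stromal cells were clustered again, 113 young and 0 aged chondrocyte-like cells fell into a subcluster led by Col9a2, Col9a1 and Col2a1, and 32 aged and 28 young cells shared another. Of the rest, 5 aged cells fell into a mostly fibroblast-like subcluster of aged cells alone, whose leading genes included Ccl2, Irf1, Ier3, Atf3 and Nfkbia. A subcluster led by Lyz2, with S100a8 and Camp among its leading genes, took 2 aged and 7 young cells, and 2 young cells joined a fibroblast-like one led by Postn. Without these cells, 32 aged and 141 young cells gave ratios of 1.79 for Atf3, 4.14 for Ier3, 3.93 for Nfkbia and 3.73 for Irf1. Lum was then at 7.25 (5.62 to 9.58, 3 young counts), Dcn at 3.40, Camp at -4.98 (1 aged count), Lyz2 at -2.23 and Col1a1 at -9.21, and Angptl7 turned to -0.52. In the shared subcluster the Atf3 ratio was 1.07 (0.85 to 1.28) and the Col2a1 ratio -5.88 (-6.84 to -5.07), but Col1a1 still stood at 9.11 against 28992 CPM. Angptl7 turned to -3.07 there.

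The next question, taken from the study's title, concerned how many chondrocytes express Atf3. The study picked this gene on these libraries, so its direction is not independent evidence. After each cell was thinned to 2000 UMIs, 26 of 38 aged chondrocyte-like cells had an Atf3 UMI (68.4%, 51.3 to 82.5), against 59 of 150 young cells (39.3%, 31.5 to 47.6). In the shared stromal subcluster 24 of 31 aged cells (77.4%, 58.9 to 90.4) and 15 of 28 young cells (53.6%, 33.9 to 72.5) had one, so the intervals overlapped there. Without thinning the shares were 82.1% and 58.7% in the whole class, at median depths of 6781 and 14832.5 UMIs; 1 aged cell was too shallow to be thinned. B cell-like cells, taken as background, had an Atf3 UMI in 2.67% of aged and 1.08% of young cells after thinning, at median depths of 2053 and 3131 UMIs. Only 28 of their 546 aged Atf3 counts lay outside a plasma-type cluster described below, so the aged share is no plain background level. Cdkn1a was found in 36.8% of aged (21.8 to 54.0) and 13.3% of young chondrocyte-like cells (8.34 to 19.8), and without thinning in 53.8% and 43.3%. Cdkn2a was found in 0 of 38 and 0 of 150 cells, which at 3 counts of the total allows shares of up to 7.89% and 2.00% of cells with a UMI.

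Other stromal and myeloid cells held Atf3 too. After thinning it was found in 45.7% of aged and 32.1% of young fibroblast-like cells, in 54.5% of 33 aged and 33.3% of 12 young endothelial-like cells, and in 29.3% and 29.9% of macrophage or monocyte-like cells.

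**Figure D4:**
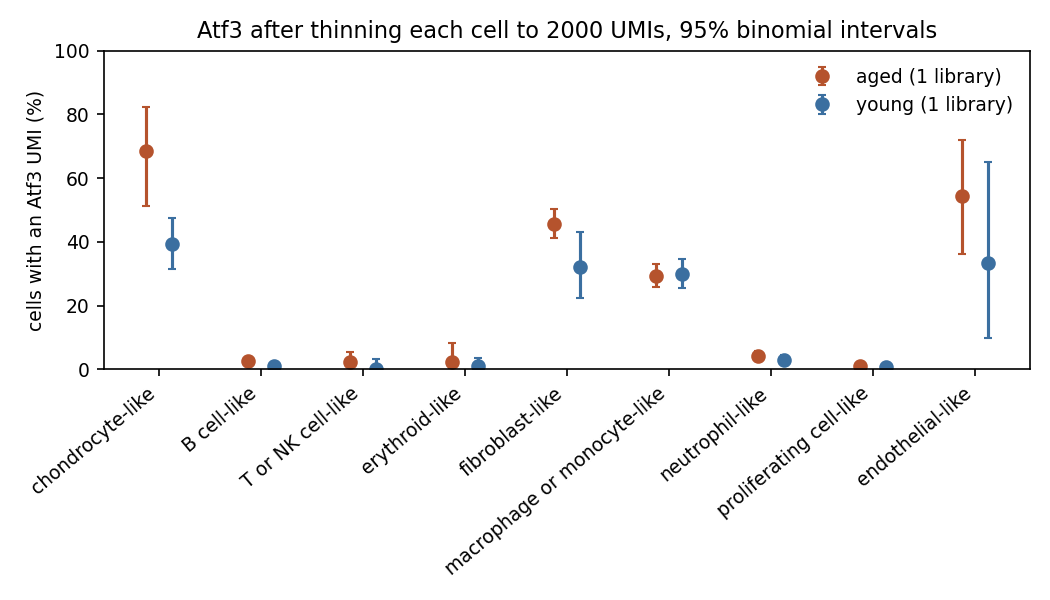
Share of cells with at least 1 Atf3 UMI (%, y axis) after thinning to 2000 UMIs, by cell class (x axis) and library; error bars are exact 95% binomial intervals. Chondrocyte-like cells are at 68.4% in aged and 39.3% in young, and macrophage or monocyte-like cells at 29.3% and 29.9%.

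Cells with Atf3 were then compared with the other chondrocyte-like cells of the same library. Cdkn1a and Atf3 were found together in 10 of 38 aged and 12 of 150 young cells, with odds ratios of 1.25 and 2.65; at 1000 UMIs these were 5.29 and 2.89, so few cells decide the aged value. The AP-1 and immediate early list, counted without Atf3, took 5.26% of UMIs in aged cells with Atf3 and 4.14% in those without, and 3.98% and 2.43% in young cells. The cartilage matrix list took 5.98% against 8.54% in aged cells, and 7.74% against 7.11% in young cells. At 1000 UMIs it took 6.35% against 7.19% in aged and 7.99% against 7.09% in young cells, so the aged difference is smaller there. Senescence genes took 1.48% against 1.41% in aged cells and 1.07% against 0.811% in young cells, and in young cells at 1000 UMIs 1.24% against 0.811%.

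In fibroblast-like cells Atf3 stood at 1382 CPM in aged and 268 CPM in young cells (log2 ratio 2.37), Prg4 was higher by 3.02 and Cdkn1a was at -0.26 (-0.55 to 0.025). Tnn, an extracellular matrix glycoprotein, was higher by 8.74 (6.26 to 14.05, 1 young count), the apolipoprotein gene Apod by 8.65 (6.79 to 11.70, 2 young counts), Cxcl10 by 6.94 and Ifit3 by 5.31 (3.75 to 7.60, 3 young counts), and Serpina1 was at least 42.0-fold higher. Cpz (-5.14), Postn (-4.50), Col1a1 (-4.26), the osteoblast gene Bglap (-4.18) and C1qtnf6 (-4.13) were lower. The senescence list had a median of 0.81 (-0.11 to 1.36) and the AP-1 list of 1.26 (0.73 to 1.67), each above all random lists, with 12 of 18 and 29 of 38 members higher. Cdkn2a had 12 aged and 0 young counts, at least 1.92-fold higher. The young cells came largely from cluster 23, which held no aged cell. With each library clustered on its own 55 aged cells kept this name, and Atf3 turned to -1.34, Prg4 to -1.60, the AP-1 median to -0.43 and the senescence median to -0.77.

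Macrophage or monocyte-like cells differed in inflammatory genes. Spp1, which encodes osteopontin, was higher in aged cells by 6.90, Acod1 by 5.55, RT1-Bb by 5.50, the metallothionein Mt2A by 5.36 and Nos2 by 5.11, and Lilrb3a (-4.53), Siglech (-3.09), Niban3 (-3.00), Cd79b (-2.56) and Gchfr (-2.53) were lower. Siglech is on the dendritic cell marker list and Cd79b on the B cell list, so no difference of macrophages is read from either. RT1-Bb encodes a class II chain, and the gene of its partner chain, RT1-Ba, stood at -0.083 in these cells. RT1-Bb is therefore not read as an inflammatory difference. The secreted inflammatory list had a median of 1.85, with 24 of 28 members higher. Cdkn1a was higher by 1.56 (1.41 to 1.72) and Atf3 was at -0.16 (-0.26 to -0.058), where TMM scaling would add 0.14 and resolution 0.5 gave 0.53.

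B cell-like cells of the aged library included a plasma-type cluster of 442 cells against 33 young cells, which held 70.5% of the aged and 5.79% of the young UMIs of the class. The median log2 ratio of all genes in the class was -1.38, and TMM scaling would add 1.35. Most lists stood high among random lists, which were drawn from the same class and so already share that shift. Because the plasma-type cluster weighs so unevenly on the libraries, no list is singled out. Cxcl10 was higher by 11.79 (10.24 to 14.07, 3 young counts), Tmem176a by 6.999, Hspb1 by 6.44, Lmna by 5.17 and RT1-Bb by 4.44, while Col1a1 (-4.89), Sparc (-4.82), Vpreb2 (-3.55) and Aebp1 (-3.33) were lower. Col1a1 lay between 18.7 and 51.4 CPM and Sparc between 20.7 and 69.6 CPM in every compared young class other than chondrocyte-like and fibroblast-like cells, against 47771 and 23655 CPM in young fibroblast-like cells, so no difference of B cell-like or neutrophil-like cells is read from either gene. Atf3 was higher by 2.70. Once the plasma-type cluster was left out, the ratios were 5.53 for Cxcl10 (3.52 to 8.65, 2 young counts), 2.53 for Tmem176a, 1.87 for Hspb1, 2.10 for Lmna, 5.78 for RT1-Bb, -1.87 for Vpreb2, -1.88 for Aebp1 and 0.11 for Atf3 (-0.55 to 0.72), nearer to 0 than with it for all of these but RT1-Bb.

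In T or NK cell-like cells RT1-Bb was higher by 7.80 (5.94 to 10.85, 2 young counts), the death ligand Faslg by 2.80, Rora by 2.55 and Txndc5 by 2.47, and Jchain, a plasma cell gene that was among the leading genes of the plasma-type cluster, was at least 39.1-fold higher. Genes of B cells and other antigen-presenting cells moved with these, with Cd74 higher by 1.43, RT1-Da by 1.58, RT1-Ba by 1.96 and RT1-Db1 by 1.99. Of the B cell markers Mzb1 was also higher (2.40), while Cd79b was at -0.28 (-0.71 to 0.15). The killer cell receptor genes Klra22 (-2.94), Klrb1b (-2.76) and Klre1 (-2.56) were lower, as were the erythroid genes Ahsp (-5.18) and Car2 (-2.73). Erythroid genes went both ways, since Hbb (7.12) and Hba-a1 (0.63) were higher, so no difference of T or NK cell-like cells is read from them. In neutrophil-like cells Cdkn2b, an inhibitor of cyclin-dependent kinases, was higher by 5.97, RT1-CE5 by 4.48, Acod1 by 4.28, Gpnmb by 3.92 and RT1-A1 by 3.84, while Sparc (-5.25), Lilrb3a (-2.77), Gm2a (-2.68), Klf4 (-2.16) and Eid1 (-2.04) were lower. Erythroid-like cells had more RT1-T24-4 (4.47), Rcn2 (3.16), Lcn2 (3.10, and -0.13 with 1000 genes and 10% mitochondrial counts), RT1-A1 (2.97) and Ifi27 (2.53) and less Retnlg (-4.93, -7.99 to -3.06, 2 aged counts), Alox15 (-3.55), Vrk2 (-2.75), Tcp11l2 (-2.29) and Tent5c (-1.83). Retnlg is a neutrophil marker and Lcn2 a leading gene of a neutrophil-like cluster, so no difference of erythroid-like cells is read from either. Proliferating cell-like cells had more Pmepa1 (4.02), Ifi27 (3.12), RT1-CE5 (2.76), Gbp5 (2.03) and Snap29 (2.01) and less RT1-Db1 (-2.85), Pde6h (-1.79), Tspan13 (-1.71), Gm2a (-1.70) and Tuba1c (-1.67). Interferon response medians stood above all random lists in fibroblast-like (0.96), macrophage or monocyte-like (0.33), neutrophil-like (0.73) and proliferating cell-like cells (0.76), as did other lists, the secreted inflammatory list in the first 3 of these. TMM scaling would add 0.24 in T or NK cell-like, 0.23 in neutrophil-like and -0.20 in erythroid-like cells. Values of RT1 genes and of other multigene families such as Klra22, Lilrb3a and Defa5 are uncertain, since reads can be split between near-identical copies.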

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

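The handling test and the restriction to a shared subcluster were chosen only after the data were seen; what would argue against subtypes was written down after the subclusters were known but before any ratio in the shared one was. The conditions that the shared cells be matched and that the macrophage bound hold under every scaling were added once the values of those tests were known.

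Prg4 went opposite ways in the chondrocyte-like class (1.06, but -1.87 with each library clustered on its own) and in neutrophil-like cells (-1.79, -3.34 to -0.52). In neutrophil-like cells it rests on 6 aged and 33 young counts. Young neutrophil-like cells held 7.18 CPM, within the 1.97 to 11.1 CPM of the other compared young blood and proliferating classes. No difference of neutrophil-like cells is therefore read from Prg4, and the difference between classes was not tested. Among the 2337 aged and 1144 young barcodes left out, 11 aged and 8 young ones held at least 10 counts of the 22 chondrocyte markers, above the limit of 3 that a count of 0 allows. Among kept cells 385 aged and 229 young ones passed the same minimum, more than the 39 and 150 of the class, so it does not mark chondrocytes and nothing is drawn from it.

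Atf3 was higher in aged chondrocyte-like cells, at a log2 ratio of 1.61. Depth per cell is argued against, since after thinning the lower bound of the aged share lay 3.72 percentage points above the upper bound of the young share. The aged cells were the shallower ones, at a median of 6781 against 14832.5 UMIs. Greater depth could therefore not have raised their share even before thinning, so the thinning adds little. Different subtypes in the class may contribute: in the shared subcluster the lower bound was still 0.85, the outcome set as evidence against them before that ratio was known, but that bound assumed matched cells, Col1a1 there stood at 9.11 against 28992 CPM, and the intervals of the thinned shares overlapped there (77.4% and 53.6%). A handling response of the aged library stays open. In macrophage or monocyte-like cells the upper bound was -0.058, the outcome set as evidence against it. However, TMM scaling would add 0.14, and resolution 0.5 gave a ratio of 0.53. The interval lay above 0 in 5 of 8 classes, but these include the chondrocyte-like class itself. The others were fibroblast-like, erythroid-like and B cell-like cells, and T or NK cell-like cells with 1 young count. The B cell-like ratio was 0.11 without the plasma-type cluster. Age itself stays open as well and was not tested apart from these.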

How the results depend on the processing

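No paired analysis was possible because both libraries carry only replicate 1 and the results come from no test. Of the values that answer a comparison, 348 stayed within their interval under another setting, 101 moved beyond it and 3 changed sign; of the other values 1830 stayed, 403 moved and 15 changed sign. Changes of sign are counted only where the interval excluded 0, so the 101 include the fibrous matrix median (-1.32) and the Atf3 ratios of neutrophil-like (0.25) and proliferating cell-like cells (-0.15), which also turned. In chondrocyte-like cells the Atf3 ratio kept its direction under all 19 alternatives (0.92 to 1.85), as did Col2a1 (-10.97 to -5.88). Alternatives on subclusters, combined classes, Ptprc, top doublet scores and the plasma-type cluster, and all settings for genes of the other classes, were chosen after seeing the data. Keeping the called doublets left the sizes of the chondrocyte-like and fibroblast-like classes as they were and moved the young unnamed share to 6.47%. Unless stated, the cause was not tested.

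With 200 genes and 20% mitochondrial counts, aged shares were 36.8% for B cell-like, 11.3% for fibroblast-like, 4.03% for erythroid-like, 8.97% for macrophage or monocyte-like, 0.883% for mast cell-like, 16.04% for neutrophil-like and 6.24% for proliferating cells. Young shares were 53.1% for B cell-like, 4.95% for erythroid-like, 8.11% for proliferating and 11.2% for unnamed cells. With 1000 genes and 10%, shares in aged and young were 23.9% and 57.8% for B cell-like, 0.918% and 2.06% for chondrocyte-like, 14.6% and 1.23% for fibroblast-like, 3.73% and 4.49% for neutrophil-like, 4.47% and 9.67% for proliferating and 29.7% and 16.2% for unnamed cells. The aged macrophage or monocyte-like share was then 16.1%, the aged mast cell-like share 0.622% and the young erythroid-like share 1.62%. Atf3 ratios were 3.30 in B cell-like, -0.26 in macrophage or monocyte-like, -0.38 in neutrophil-like and 1.38 in proliferating cells, Prg4 was 2.86 in B cell-like and Lcn2 -0.13 in erythroid-like cells.

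At resolution 0.5 shares in aged and young were 4.24% and 2.46% for macrophage or monocyte-like, 14.8% and 14.9% for proliferating and 13.1% and 7.69% for unnamed cells, the aged B cell-like share was 39.4%, and the macrophage or monocyte-like Atf3 ratio was 0.53. At resolution 2 they were 38.7% and 53.7% for B cell-like, 9.22% and 3.88% for macrophage or monocyte-like and 12.8% and 9.97% for unnamed cells, with 3.35% for aged erythroid-like and 12.7% for young proliferating cells and an Atf3 ratio of -0.27 in macrophage or monocyte-like cells. Without the top 8% of doublet scores aged shares were 43.5% for B cell-like, 10.4% for proliferating and 8.06% for unnamed cells, the Cdkn1a ratio was 1.10, and Atf3 ratios were 2.76 in fibroblast-like and -0.53 in macrophage or monocyte-like cells. With stress genes out of the clustering, shares in aged and young were 8.22% and 10.2% for proliferating and 11.9% and 8.13% for unnamed cells, and the young B cell-like share was 57.7%.

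With each library clustered on its own, the main aged stromal cluster took the chondrocyte-like name. Aged shares were then 7.89% for chondrocyte-like, 0.904% for fibroblast-like, 3.37% for erythroid-like, 8.99% for macrophage or monocyte-like and 7.95% for proliferating cells. Young shares were 55.1% for B cell-like, 1.24% for mast cell-like, 9.21% for proliferating and 10.8% for unnamed cells, and 0% for endothelial-like cells, since no young cluster took that name. Ratios in chondrocyte-like cells were -0.058 for Cdkn1a, -10.97 for Col2a1, 0.93 for Camp and -1.87 for Prg4. List medians were -4.61 for cartilage matrix, 1.03 for fibrous matrix, 0.099 for oxidative phosphorylation and 0.31 for lysosome and autophagy. In fibroblast-like cells Atf3 was -1.34, Prg4 -1.60 and the AP-1 median -0.43, and the Atf3 ratio was -0.42 in macrophage or monocyte-like and 1.00 in proliferating cells.

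With TMM and with median-of-ratios scaling the Atf3 ratio was 1.82 and 1.85 in chondrocyte-like, 4.05 and 4.08 in B cell-like, and -0.015 and -0.0041 in macrophage or monocyte-like cells. As a mean of per-cell CPM it was 1.23 in B cell-like and 2.14 in fibroblast-like cells. After thinning it was 1.70 in B cell-like and 1.87 in fibroblast-like cells, and at least 0.80 in T or NK cell-like cells, where no young count was left.

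In the shared stromal subcluster ratios were 1.07 for Atf3, 0.39 for Cdkn1a, -5.88 for Col2a1 and -3.07 for Angptl7, the fibrous matrix median -2.91 and the young Atf3 share 53.6%. With stress genes out of that clustering they were 0.92 for Atf3, 0.30 for Cdkn1a, -6.07 for Col2a1 and 0.18 for Col9a2, with a share of 51.9%. Without cells of subclusters mostly of other classes, Atf3 was 1.79 and Angptl7 -0.52. Over chondrocyte-like and fibroblast-like cells together ratios were 0.044 for Cdkn1a, -10.47 for Col2a1 and 0.38 for Camp, with medians of -4.10 for cartilage matrix, 0.017 for oxidative phosphorylation and 0.18 for lysosome and autophagy, and an aged Atf3 share of 48.8%. The young Atf3 share was 26.7% at 1000 UMIs and 58.7% without thinning, as fewer or more UMIs per cell set it. Without the plasma-type cluster the B cell-like ratios were 0.11 for Atf3 and -0.058 for Cdkn1a. Depth limits genes with few aged counts in the chondrocyte-like class, whose aged sum held 290776 UMIs, to wide intervals or bounds.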

Other observations

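The free RNA and shared-read tests, the restriction to a shared subcluster and the pairing of RT1-Bb with RT1-Ba were chosen only after the data were seen. What would argue against subtypes was written down after the subclusters were known but before any ratio in the shared one was, and the reasons for not relying on the subcluster and strain bounds were found once their values were known.

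RT1-Bb and RT1-Ba encode partner chains of a class II molecule. In macrophage or monocyte-like cells RT1-Bb stood at 1012 CPM in aged and 22.3 CPM in young cells, while RT1-Ba stood at 1014 and 1074 CPM (log2 ratio -0.083). In B cell-like cells RT1-Bb was higher by 4.44 and RT1-Ba was at -0.047. Cdkn2a, with no count in chondrocyte-like cells, had 50 aged and 37 young counts in proliferating cell-like cells (log2 ratio 2.20, 1.55 to 2.85).

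Col2a1 was lower in aged chondrocyte-like cells, at a log2 ratio of -7.59. Free RNA in the young library is argued against, since Col2a1 in young B cell-like cells reached 0.0903% of its level in young chondrocyte-like cells. Different subtypes may account for part of it: 113 young cells formed a Col2a1-rich subcluster without aged cells. In the shared subcluster the upper bound was still -5.07, the outcome set as evidence against subtypes before that ratio was known, but Col1a1 (-11.64) and Prg4 (2.96) differed there too, so the cells were not matched and the test does not settle it. Age stays open and was not tested apart from the make-up of the class.

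Hbb (over 4-fold in 8 of 8) and RT1-A1 (over 4-fold in 4 of 8, log2 ratios 0.53 to 4.51) were higher in aged cells of all 8 compared classes. Other class I genes went both ways. In macrophage or monocyte-like cells RT1-A2 was at -1.17 and RT1-CE10 at -0.56. In B cell-like cells they were at -1.78 and -0.86, where TMM scaling would add 1.35. RT1-CE10 was higher by 0.89 in neutrophil-like cells. In erythroid-like cells Hbb was at 158301 CPM in aged and 1963 CPM in young cells and LOC100134871, named Hbbl1 in the GRCr8 gene table, at 40221 and 260416 CPM, while the sum of 3 beta-globin genes differed by 1.32-fold, as reads split between paralogs may give; no such sum was made for class I genes. A split is argued against as the whole difference in fibroblast-like cells, where the sum was 20.8-fold and Hba-a1 13.2-fold higher in aged cells, and in the other 6 classes the sum differed by 1.14-fold to 2.27-fold, higher in aged in 2 and lower in 4. For a strain or haplotype difference, 18.5% of the 108 genes over 16-fold apart in a class differed over 4-fold the same way in every class that measured them (62.0% in direction alone), which met the bound of under 50% set beforehand as evidence against it but is not relied on, because the 108 genes include ones such as Col2a1 that go with the make-up of a class, while Hbb itself was over 4-fold higher in every class. Hbb is an erythroid marker, and how far its counts in the other classes were free RNA of the same library was not tested. The classes may therefore not be separate observations of Hbb. Strain is not in the labels, so strain and age cannot be told apart here, and age was not tested.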
